A study of Mus musculus with 3 samples.

How the data were processed

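RNA-seq was performed on 3 mammary tumours of the FVB-MMTV-Neu mouse strain, in which a rat Neu (Erbb2) transgene is driven by the mouse mammary tumour virus promoter. Per the labels' protocols, tumours were transplanted orthotopically into syngeneic hosts, reached a diameter of 5 mm and were left untreated for 7 days. The series' design text instead has the tumours come from untreated MMTV-Neu mice, so it is uncertain what host tissue surrounded them. Total RNA was extracted with a Qiagen RNeasy kit and checked on a Bioanalyzer, libraries were prepared with the Illumina TruSeq mRNA kit, and paired-end reads of 50 bp were obtained on a HiSeq instrument. The labels put all samples in 1 group of untreated tumours. They are called tumours 1, 2 and 3 here, in the order of deposition, and the numbers pair nothing. The labels do not say whether the tumours came from separate donor mice.

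The authors deposited estimated counts per gene symbol, which are Salmon read numbers per the file headers, without scaling for depth or gene length. Per the submitters' processing notes, STAR, SAMtools and Picard were also used, with genome build mm10. Their versions, the annotation release, the way transcripts were summed to genes and the strand setting are not given in the sources used here. Without a strand setting, reads of a gene and of its antisense partner cannot be told apart. Each table held 47480 gene symbols. The file headers place tumour 1 in lane 1 and tumours 2 and 3 in lane 5 of the same run, so that lane coincides with the difference between tumour 1 and the others, and the values without tumour 1 are the values within 1 lane.

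The estimated counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR 4.0.16 (R 4.3.3) with its defaults of a minimum count of 10 and a minimum total of 15, which in 1 group of this size requires a gene to be present in all 3 libraries. The count of 10 is applied as a CPM, so the count needed differs with library size. Gtf2h2 passed with 7 counts in tumour 2, whereas Tnnt3 did not with 25 counts in tumour 1. The filter left 12710 genes. Genes close to 0 in 1 tumour, among them most skeletal muscle genes, did not pass and were described by gene only. The library totals of these genes were scaled with TMM factors of 1.48, 0.722 and 0.936 for tumours 1, 2 and 3. Levels are CPM of the scaled totals, from the cpm function of edgeR. Log2 CPM used a prior count of 2. Because 1 group allows no comparison of conditions, the analysis described levels and the spread between tumours. The biological coefficient of variation was the square root of edgeR's common dispersion in a negative binomial model with an intercept only. Each gene's counts were tested against the scaled library totals with a chi-square test, Benjamini-Hochberg adjusted at 0.05, which compares these libraries and not conditions. A gene was said to lie apart in a tumour when its log2 CPM was at least 2 (4-fold) above or below both other tumours.

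For 33 gene lists, the median over members of log2 CPM minus the mean of the other tumours was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart at a percentile up to 2.5 or from 97.5. Lists with fewer than 5 members past the filter were given by gene. The same was done for the median SD of a list's members over the tumours. Luminal and basal lists were compared within tumours with an exact two-sided sign-flip permutation test. The genes named below were set by a rule. It takes Erbb2, the 3 members of each list with the highest mean CPM and the member with the largest range, 11 fixed markers, the 10 highest genes of all, and for each tumour the 8 genes farthest above and the 4 farthest below both others. Predicted genes, pseudogenes and immunoglobulin or T cell receptor segments were counted but not named, except among the 10 highest genes. A gene named outside this rule is marked as chosen after its values were seen, and 2 genes that the rule takes are not reported here. The groups, tests, lists, naming rule and a first set of alternatives were fixed before the data were examined. The lists covered ErbB receptors and ligands, Erbb2 chromosomal neighbours, MAPK pathway output, 4 kinds of mammary epithelial genes, milk proteins, mesenchymal transition, proliferation, Wnt and p53 targets, stress and hypoxia, interferon response, MHC classes and immune checkpoints, sex-linked genes and markers of immune, stromal, vascular, nerve, muscle, skin, fat and red blood cells.

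Positions, transcript lengths and GC contents came from the GENCODE M21 annotation of GRCm38, the assembly also named mm10. Of the symbols, 45213 were matched, and 12343 of the genes past the filter (97.1%) had a length and a GC content, taken from the longest transcript. The alternatives fixed at the start were DESeq2 1.42.0 size factors and dispersions, scaling by total count, other filters, prior counts of 0.5 and 10, thresholds of 2-fold and 8-fold, list means and each tumour left out. Alternatives added after seeing the data were a filter of a mean CPM of at least 1, removal of the median trend with GC content and transcript length (20 bins each), counts thinned to the smallest library, library totals without the skeletal muscle list and Rn18s-rs5, and the basal list without smooth muscle genes. Clustering of genes along chromosomes was tested in windows of 10 neighbouring protein-coding genes against 10000 shuffled gene orders. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

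The dispersion estimate, the counting-noise test, the 4-fold rule and the list difference were tested on simulated counts with the real means and library sizes over 12710 genes. The list spread, the luminal and basal comparison and the GC and length correction were not simulated. A simulated coefficient of variation of 0.6 was estimated as 0.597. Of 100 genes raised 8-fold in tumour 1, the counting-noise test recovered 100 and the 4-fold rule 100. Of 100 genes raised 2-fold, the counting-noise test recovered 97, and the 4-fold rule took 0. For the lists, variation between tumours was added to the counting noise. It was drawn for each gene alone at 0.331, the coefficient of variation without tumour 1. All 14 of 14 lists raised 4-fold in tumour 1 stood apart, as did 4 of 42 list and tumour pairs left unchanged in the same libraries. Depth sets the precision. A floor of 3 counts corresponded to 0.0434 CPM in tumour 1, 0.373 CPM in tumour 2 and 0.191 CPM in tumour 3. The 95% Poisson intervals given below and these floors cover counting error only, since the reads carried no molecular identifiers.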

Results

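The transcriptomes of 3 untreated MMTV-Neu mammary tumours were measured, with 1 library per tumour and no second group. Total estimated counts were 47449153 in tumour 1, 11388769 in tumour 2 and 17147394 in tumour 3, spread over 22991, 16696 and 18273 genes with a count above 0. The data give the level of each gene and the spread between tumours. No difference between single tumours has a replicate check, and no p-value given for such a difference rests on replicates.

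The tumours carried an epithelial program with even Erbb2 levels. Erbb2 (chromosome 11, 98412470 to 98437716), the mouse ortholog of the rat transgene with which it can share reads, was at 75.5, 104 and 93.6 CPM in tumours 1, 2 and 3, or 91.1 ± 14.5 CPM (SD, n = 3). Its partner receptor Erbb3 was at 55.3 ± 17.5 CPM and the ligand gene Tgfa at 22.8 ± 5.83 CPM. The ligand gene Nrg1 ranged most, at 11.9, 0.497 and 1.33 CPM, below the filter. The luminal keratin Krt8 (chromosome 15, 101996698 to 102004482) was at 407, 734 and 1038 CPM, Krt18 at 461, 245 and 453 CPM, and the claudin gene Cldn7 at 136, 278 and 382 CPM. The estrogen receptor gene Esr1 was at 4.61 ± 1.60 CPM. The collagen gene Col1a1 reached 2299 ± 1210 CPM, with 3695 CPM in tumour 2. Transcripts of T cells were scarce. Cd3e was at 0.995 ± 0.605 CPM, Cd8a had 19, 1 and 2 counts, and Cd274, which encodes PD-L1, was at 2.43 ± 0.687 CPM. Of the sex-linked genes, Xist was at 272, 109 and 76.6 CPM, and the Y-linked Ddx3y and Uty had 0 counts in all 3 libraries, which allows up to 0.373 CPM in tumour 2, the shallowest.

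**Figure D1:**
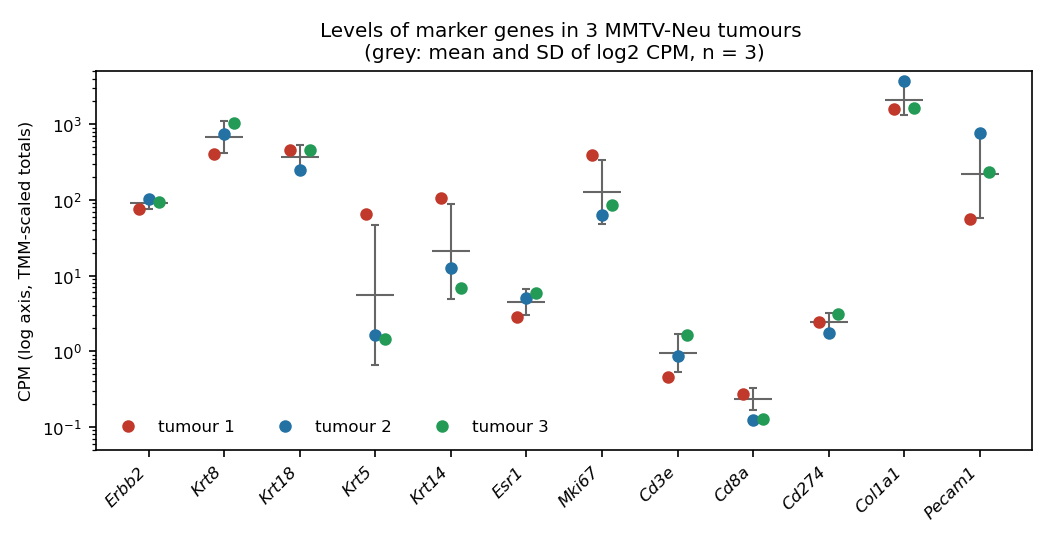
Levels of the fixed marker genes in CPM on a log axis. Points are the 3 tumours, and grey marks are the mean and SD of log2 CPM (n = 3). Erbb2 lay between 75.5 and 104 CPM, whereas Krt5 was at 64.4 CPM in tumour 1 and at 1.62 and 1.46 CPM in tumours 2 and 3.

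The highest genes of all differed in rank between libraries. Rn18s-rs5, a symbol of ribosomal RNA sequence, took 0.20% of counts in tumour 1, 7.87% in tumour 2 and 6.68% in tumour 3. It was followed in mean CPM by Ckm, the predicted genes Gm26917 and Gm42418, the ribosomal protein genes Rplp1, Rpsa and Rplp2, Actb, the predicted gene Gm28437 and the lysosomal protease gene Ctsd. Values of the predicted genes and of Rn18s-rs5 are uncertain, since such sequences can share reads with near-identical copies. Ribosomal protein genes held 7.29, 9.62 and 11.7% of counts, and the 10 highest genes of each library held 6.74, 21.0 and 13.8%. Tumour 1 had relatively more counts from long transcripts of low GC content. Its count-weighted mean transcript length was 3408 bases against 2970 and 2821, and its GC content 50.4% against 53.7 and 52.5%. Across 12343 genes, which are not independent replicates, the difference of tumour 1 from the others fell with GC content (Spearman rho −0.30) and grew with transcript length (rho 0.24).

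**Figure D2:**
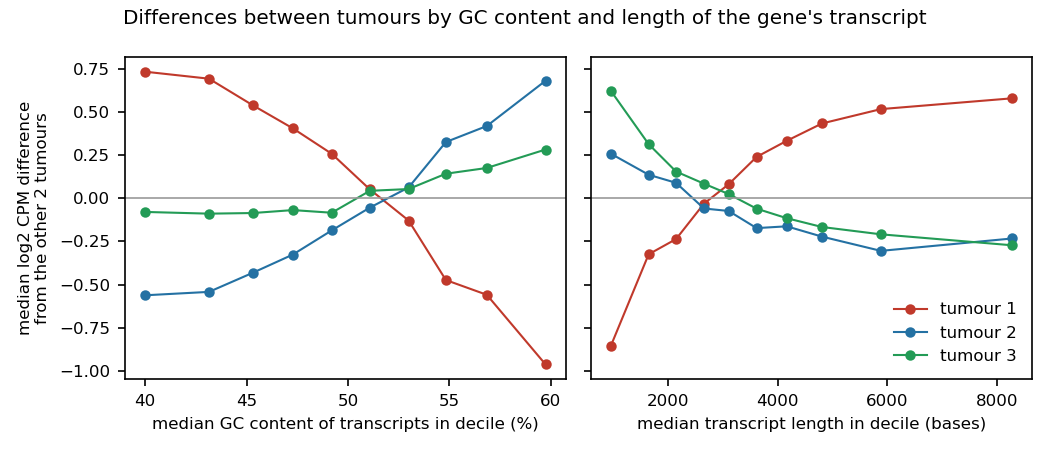
Median log2 CPM difference of each tumour from the mean of the other 2, by decile of GC content (left, percent) and of length (right, bases) of the gene's longest transcript. The GC deciles of tumour 1 run from 0.73 in the lowest to −0.96 in the highest.

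Most of the spread between tumours set tumour 1 against the others. The biological coefficient of variation was 63.5% over the 3 tumours and 33.1% without tumour 1, that is, within the lane shared by tumours 2 and 3. Across genes, log2 CPM of tumours 2 and 3 correlated with r = 0.95, of tumours 1 and 2 with r = 0.65, and of tumours 1 and 3 with r = 0.75. Of 12710 genes, 11968 (94.2%) differed between the libraries by more than counting noise (chi-square test, Benjamini-Hochberg adjusted). The median SD of log2 CPM was 0.72, against 0.06 in libraries simulated with counting noise alone. Separate tumours are bound to exceed counting noise, so these values do not tell ordinary variation between tumours from more. For 3755 genes (29.5%) the highest and lowest tumour were at least 4-fold apart.

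Tumour 1 had 769 genes at least 4-fold above and 1043 at least 4-fold below both other tumours, together 14.3% of genes. Among genes past the filter, those farthest above were Cul4a, the scaffold of a cullin-RING ubiquitin ligase, at 1792 CPM (95% Poisson interval 1783 to 1802) against 18.3 and 20.5 CPM, the fibroblast growth factor receptor gene Fgfr3 at 79.3 against 1.74 and 0.763 CPM, the kininogen gene Kng2, the cytochrome P450 gene Cyp1b1, the basal keratin Krt5, the receptor tyrosine kinase Kit at 184 against 4.47 and 4.77 CPM, Tfdp1, an E2F dimerization partner, at 106 against 2.86 and 2.03 CPM, and Mdm2, the ubiquitin ligase of p53, at 522 CPM (517 to 528) against 6.46 and 15.2 CPM. Cul4a (13105621 to 13147940) and Tfdp1 (13338751 to 13378448) lie in 1 region of chromosome 8. Mdm2 lies on chromosome 10 (117688875 to 117710758). Other genes near these, chosen after their values were seen, were higher, went the other way or hardly differed. Lamp1, next to Cul4a, was at 13542 CPM in tumour 1 against 748 and 666 CPM. Also between Cul4a and Tfdp1, Grtp1, below the filter, was at 44.4 against 0.497 and 1.14 CPM, Dcun1d2 at 12.4 against 4.47 and 5.66 CPM, Tmco3 at 16.7 against 5.22 and 4.45 CPM, and Adprhl1, below the filter, at 0.0145 against 9.20 and 5.21 CPM. Cct2, near Mdm2, was at 3795 against 51.7 and 134 CPM. The gene Cpm, next to Mdm2, was at 7.17 against 6.09 and 6.42 CPM. The genes farthest below, again among those past the filter, were the muscle creatine kinase gene Ckm, with 33 counts against 263510 and 182608, the muscle calcium pump gene Atp2a1, with 35 counts against 24390 and 26423, the calpain gene Capn12, and the growth factor gene Igf2, at 0.867 CPM against 638 and 959 CPM. The balance of the 2 directions depends on the scaling, the filter and the threshold. The share above in tumour 1 was 59.2% without a filter, 51.6% at 2-fold and 32.6% at 8-fold. With library totals alone, tumour 1 had 2060 genes above and 458 below (81.8% above, compared with 42.4%), since that scaling shifts the median difference of all genes by 0.84 in tumour 1, −0.70 in tumour 2 and −0.14 in tumour 3 on the log2 scale. Against only tumour 3 the counts were 1255 above and 1368 below, and against only tumour 2 they were 1981 and 1879.

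**Figure D3:**
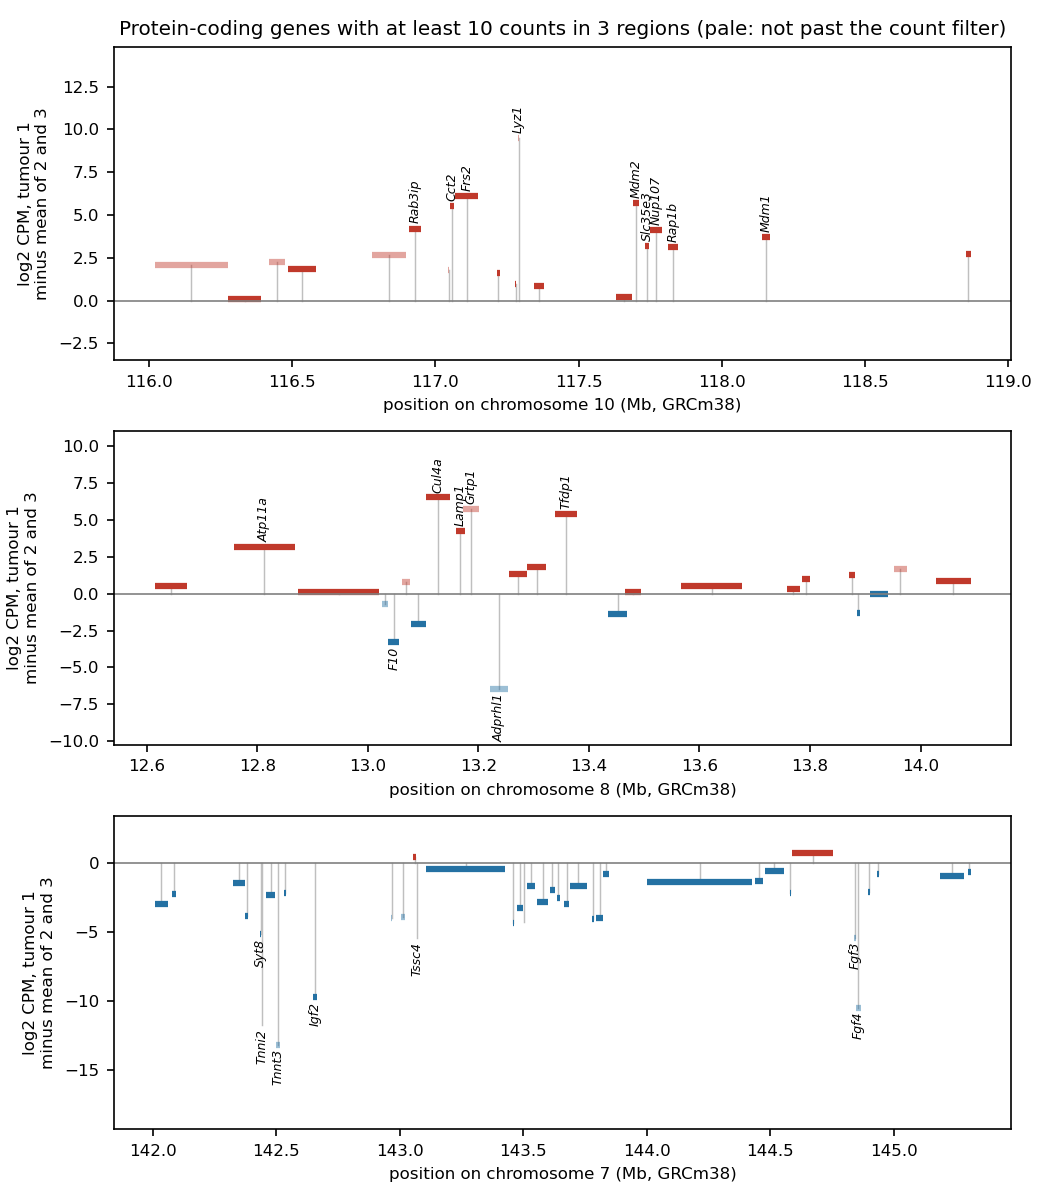
Log2 CPM of tumour 1 minus the mean of tumours 2 and 3 for protein-coding genes with at least 10 counts in a library, in 3 regions of GRCm38 (position in Mb). Each bar spans a gene, and pale bars did not pass the count filter. Mdm2 on chromosome 10 stands at 5.71, Cul4a on chromosome 8 at 6.53 and Igf2 on chromosome 7 at −9.71.

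Tumours 2 and 3 had far fewer genes apart. Tumour 2 had 32 genes above and 75 below both others. Those farthest above were the acute-phase gene Saa3 at 260.0 CPM against 5.26 and 24.9 CPM, the chemokine gene Ccl22, the potassium channel gene Kcnk3, Cyp2s1, the carbonic anhydrase gene Car4, Ggn, the amino acid transporter gene Slc7a10 and the antisense gene Mypopos, whose value is uncertain for lack of a strand setting. Those farthest below were BC055324, the receptor gene Tnfrsf19 at 1.99 CPM against 72.8 and 16.7 CPM, the kappa-casein gene Csn3 at 2.61 against 437 and 19.6 CPM, and Gtf2h2, which had 7 counts in tumour 2. Tumour 3 had 10 genes above and 10 below. They were led by Dcpp1 at 86.3 CPM against 0.405 and 15.5 CPM, the interferon-induced chemokine gene Cxcl9 at 75.3 CPM (71.1 to 79.7) against 2.37 and 14.0 CPM, Insl6, the neutrophilic granule gene Ngp, Mlf1, Fam26f, Adam33 and Lyrm1 above, and by Mfsd4, Fbxo17, Dynlt1a and Tshz2 below. The scaling by library totals gave 8 above and 215 below in tumour 2 (3.59% above, compared with 29.9%) and 9 and 5 in tumour 3 (64.3%, compared with 50%), and DESeq2 size factors gave 45 and 59 in tumour 2 (43.3%). Compared with each other alone, tumour 2 had 60 genes at least 4-fold above tumour 3 and 82 below.

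Mammary lineage genes differed between the tumours. Of 28 lists scored in 3 tumours, 30 of 84 list and tumour pairs stood apart from random lists. In simulated libraries 4 of 42 unchanged pairs did. There each gene varied on its own, at the coefficient of variation without tumour 1 (33.1%). The simulated share is therefore no benchmark for real lists, whose members can vary together. The 3 differences of a list are not independent. Of the 30 pairs, 15 also stood apart with either other tumour left out, and 13 did so in every alternative that gave a value. The basal and myoepithelial list was higher in tumour 1 by a median log2 CPM of 2.20 (percentile 100), with 9 of 15 members at least 2-fold above both others and 2, Krt15 and Tagln, at least 2-fold below. Krt14 was at 107 CPM against 12.4 and 6.74, and the integrin gene Itgb4 at 288 against 23.4 and 40.0 CPM. The smooth muscle genes Acta2 (263, 370 and 245 CPM) and Tagln (93.7, 489 and 290 CPM) did not follow, whereas Cnn1 (8.34, 1.12 and 0.953 CPM), Actg2 (12.2, 9.07 and 2.86 CPM) and Myh11 (7.53, 4.60 and 1.78 CPM) were highest in tumour 1. Krt15 was at 1.01, 16.2 and 22.1 CPM. Cnn1, Actg2, Myh11 and Krt15 were chosen after their values were seen. The same list was lower in tumour 3 by −1.63 (percentile 0), and by −0.55 compared with tumour 2 alone. The luminal progenitor list was higher in tumour 1 by 1.54 (percentile 99.4), with 6 of 9 members at least 2-fold above, among them Kit, Cd14 at 114 against 6.09 and 24.4 CPM, and Sox10 at 326 against 60.4 and 113 CPM. The luminal epithelium list was higher in tumour 1 by 0.53 (percentile 99.4), but members went both ways. Of 17, 4 were at least 2-fold above both others, among them the tight junction gene Cldn4 at 170 against 10.7 and 20.1 CPM, and 2 at least 2-fold below, Cldn7 and Elf3, the latter at 24.5 against 170 and 185 CPM and chosen after its values were seen. Krt8 was lowest in tumour 1 as well. The list was lower in tumour 2 by −0.62 (percentile 0.17). Without the GC and length trend it was at 0.85 in tumour 1 (percentile 99.9) and at −0.33 in tumour 2 (percentile 2.19). The luminal progenitor list stood lower in tumour 2 (−1.54), but within the lane that difference was −0.12 (percentile 49.3). The Wnt4 gene was at 6.11, 24.9 and 14.6 CPM, the prolactin receptor gene Prlr at 17.6, 7.33 and 3.88 CPM, and Foxa1, below the filter, at 8.83, 0.373 and 1.72 CPM. Their hormone-sensing list was higher in tumour 2 by 0.99 (percentile 98.2) and by 0.75 against tumour 3 alone, and without the GC and length trend it no longer stood apart (0.70, percentile 94.99), nor without a filter (0.71), with a mean CPM of at least 1 (0.63, percentile 94.0) or against tumour 1 alone (0.84, percentile 93.5). Of the milk protein list, 3 of 12 members passed the filter, and Csn3 ranged most. Xdh was at 25.6, 3.98 and 6.74 CPM and Csn1s1 at 4.70, 0.373 and 0.381 CPM.

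Within each tumour the luminal list lay above the basal list. The difference of their mean log2 CPM was 2.06, 2.56 and 3.45 in tumours 1, 2 and 3, with a mean of 2.69 ± 0.71 (SD, n = 3), higher in 3 of 3 tumours. The exact sign-flip permutation test gave a two-sided p of 0.25, the smallest that 3 tumours allow, so this design cannot reach 0.05. Because the lists hold different genes, the difference also depends on which genes were listed. It does not measure the shares of luminal and basal cells.

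MAPK pathway output genes were higher in tumour 1 by a median of 0.9998 (percentile 99.9), but members went both ways and the mean over members was 0.38 (percentile 99.0). Of 16, 7 were at least 2-fold above both others and 2 below, the transcription factor genes Etv4 at 110.0 against 587 and 578 CPM and Fosl1 at 4.13 against 58.5 and 34.4 CPM. Of those above, the phosphatase gene Dusp4 was at 69.8 against 4.85 and 4.83 CPM and Myc at 187 against 31.4 and 45.9 CPM. Fosl1, Dusp4 and Myc were chosen after their values were seen. Phlda1 was at 346, 388 and 444 CPM, and Epha4, below the filter, at 5.28, 0 and 1.08 CPM. Ccnd1, which encodes cyclin D1, was at 674, 1097 and 1227 CPM. The proliferation list had one of the smallest spreads of all lists, with a median SD of 0.40 (percentile 0.68). Its members still went apart singly. Mki67 was at 389 CPM in tumour 1 against 62.3 and 85.4 CPM, while Cdk1 was at 113 against 378 and 467 CPM, Birc5 at 115 against 515 and 446 CPM, and Ube2c at 145 against 468 and 404 CPM. The list stood lower in tumour 2 by −0.34 (percentile 0.56), which the removal of the GC and length trend brought to 0.02 (percentile 12.3), and against tumour 1 alone it was −0.06 (percentile 8.69). Of the Wnt targets, 5 passed the filter. They stood lower in tumour 3 by −0.93 (percentile 2.09), and within the lane that difference was 0.26. Without a filter it was −0.13 (percentile 45.3), and as a mean over members −0.75 (percentile 4.57). Tcf7 was at 48.0, 4.85 and 8.01 CPM, Notum at 15.9, 9.69 and 11.5 CPM, Znrf3 at 18.2, 5.59 and 4.19 CPM, and Wnt10a, below the filter, at 6.59, 0 and 0.0636 CPM.

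In tumour 1, MHC class I, interferon response, T and NK cell and dendritic cell lists stood lower, while neutrophil markers (0.39, percentile 69.2) and MHC class II (−0.83, percentile 31.6) did not stand apart. Antigen presentation by MHC class I stood lower by −2.13 (percentile 1.06), with 8 of 11 members at least 2-fold below both others. The peptide transporter gene Tap2 was at 34.4 CPM against 1164 and 866 CPM, the immunoproteasome gene Psmb10 at 19.3 against 730.0 and 568 CPM, and H2-D1, whose reads can be shared with other class I genes, at 196 against 2185 and 2087 CPM, as can H2-K1 at 174 against 550 and 875 CPM. The interferon response list stood lower by −1.41 (percentile 0), with 12 of 20 members at least 2-fold below, among them Bst2 at 22.8 against 171 and 154 CPM, and 1, Irgm1, above at 161 against 34.6 and 67.7 CPM. The T and NK cell list stood lower by −2.25 (percentile 0.02) on 6 members, with Cd4 at 0.824 against 7.21 and 3.62 CPM, Gzma at 1.17 against 4.47 and 5.02, Lck at 12.3 against 11.9 and 22.3, and Klrb1c, below the filter, at 0.188 against 0 and 0.699. The dendritic cell list stood lower by −2.33 (percentile 0.01) on 8 members, with Batf3 at 3.53 against 53.3 and 33.3 CPM, Fscn1 at 113 against 129 and 92.5, and Itgax at 16.7 against 6.71 and 6.74. With counts thinned to the smallest library, the dendritic list no longer stood apart in tumour 1 (0.04), nor did it without a filter (−0.89, percentile 4.31), and against tumour 3 alone it was −1.31 (percentile 1.04). With thinned counts the T and NK cell list had too few members. In tumour 3, MHC class I stood higher by 1.56 (percentile 100) and by 0.70 against tumour 2 alone, MHC class II by 0.91 and 0.49, and neutrophil markers by 0.63 and 1.41. Against tumour 1 alone, class II (1.20, percentile 92.4) and neutrophil markers (0.79, percentile 94.8) did not stand apart. The neutrophil call also ended with a mean CPM of at least 5 (0.63, percentile 97.3) and without the muscle list and Rn18s-rs5 (0.32, percentile 88.7). Of class II, H2-Eb1 was at 85.4, 244 and 341 CPM, H2-Ab1 at 102, 189 and 262, Cd74 at 280, 109 and 223, and H2-DMa at 16.0, 110 and 108. Of the neutrophil markers, Lcn2 was at 2572, 624 and 1265 CPM, Mmp9 at 13.3, 176 and 74.9, Csf3r at 13.5, 23.0 and 8.71, and Retnlg, below the filter, at 0.217, 0 and 1.46. T and NK cell markers (1.20) and interferon response (1.04) also stood higher in tumour 3, but only relative to tumour 1. Against tumour 2 alone these were −0.02 and 0.09. In tumour 2, neutrophil markers stood lower by −1.31 and within the lane by −1.41, a call that ended against tumour 1 alone (−1.43, percentile 4.06) and as a mean over members (−0.59, percentile 5.62). Dendritic markers stood higher in tumour 2 by 1.48 and by 0.62 against tumour 3 alone, but not without a filter (0.42, percentile 85.8), with a mean CPM of at least 1 (0.69, percentile 89.8) or with thinned counts (0.34, percentile 75.8). Interferon response stood higher in tumour 2 by 0.47. Scaling by library totals, which shifts the median of all genes in tumour 2 by −0.70, turned it to −0.23, but its percentile stayed at 98.7. Within the lane it was −0.09. The list did not stand apart without a filter (0.21, percentile 94.5) or with a mean CPM of at least 5 (0.46, percentile 96.9) or 1 (0.32, percentile 95.6). Lists of macrophages (−0.69, 0.30 and 0.36 in tumours 1, 2 and 3) and immune checkpoints (−0.97, 0.67 and 0.48) did not stand apart in any tumour as medians, whereas as a mean over members the checkpoints did in tumour 1 (−1.18, percentile 1.64) and tumour 3 (0.52, percentile 97.8). The complement genes C1qa (161, 2426 and 1369 CPM) and C1qc (138, 717 and 518 CPM) and Lyz2 (478, 222 and 264 CPM) led the former. Cd276 (50.1, 97.6 and 87.3 CPM), Vsir (55.7, 107 and 63.6 CPM) and Lgals9 (36.6, 70.7 and 81.7 CPM) led the latter, in which Ido1, below the filter, ranged most (1.81, 0.621 and 0 CPM). Of the B and plasma cell list 4 of 15 members passed. Sdc1 was at 397, 56.1 and 66.2 CPM and Ighm at 10.6 ± 1.93 CPM, and Pou2af1 had 859 counts in tumour 1 and 0 in both others.

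The endothelial list stood higher in tumour 2 by 1.48 (percentile 100), with 7 of 13 members at least 2-fold above both others, and by 1.02 against tumour 3 alone. Pecam1 was at 775 CPM against 56.4 and 231 CPM, Plvap at 465 against 85.6 and 226 CPM, and Cldn5 at 170 against 14.4 and 54.5 CPM. In tumour 1 the list stood lower by −1.23 (percentile 0.76), a call that ended without the GC and length trend (−0.85, percentile 4.99) or without tumour 2 (−0.69, percentile 4.20). Erythroid genes stood lower in tumour 1 by −3.74 (percentile 0.02) on 5 members, with the hemoglobin genes Hba-a1 and Hba-a2, near-identical copies that can share reads, at 32.6 CPM against 1251 and 588 CPM and at 74.6 against 1779 and 944 CPM, and Hbb-bs at 71.5 against 217 and 242 CPM. They stood higher in tumour 2 by 2.31 and in tumour 3 by 1.37, and within the lane tumour 3 was below tumour 2 by −0.90. Without the GC and length trend the call in tumour 3 ended (0.57, percentile 92.2). The Schwann cell list was higher in tumour 2 by 1.14, which without the trend was 0.78 (percentile 92.4), without a filter 0.54 (percentile 92.9), with a mean CPM of at least 5 0.14 (percentile 81.1), against tumour 1 alone 0.18 (percentile 76.1) and as a mean over members 0.77 (percentile 96.5). Pmp22 was at 21.4, 108 and 83.8 CPM, Ncam1 at 13.6, 27.1 and 11.1, Mbp at 17.3, 11.9 and 7.18, and S100b, below the filter, at 10.8, 1.99 and 0.318. In tumour 3 the fibroblast and adipocyte lists stood lower by −0.33 and −0.66, and neither stood apart within the lane (−0.50, percentile 3.81, and −0.41, percentile 5.60) or against tumour 1 alone (0.02, percentile 17.1, and −0.81, percentile 6.18). Col1a2 was at 1228, 1804 and 1109 CPM, Col3a1 at 965, 566 and 402, and Pdgfra at 18.1, 84.5 and 59.3. Of the adipocyte genes, Fabp4 was at 215, 144 and 120 CPM, Lpl at 72.6, 156 and 90.4, Cfd at 135, 85.8 and 83.8, and Adrb3, below the filter, at 5.62, 0.249 and 0.699.

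Skeletal muscle transcripts were abundant in tumours 2 and 3 and close to absent in tumour 1. The 12 listed genes held 0.000979% of counts in tumour 1, 3.54% in tumour 2 and 2.02% in tumour 3, and all 12 were at least 4-fold higher in both. The fast troponin gene Tnnt3 had 25, 43899 and 43295 counts, and the parvalbumin gene Pvalb 2, 26401 and 29516. Muscle also expresses members of other lists. Tcap, a chromosomal neighbour of Erbb2, was at 0.188, 814 and 829.5 CPM, and the pericyte marker Des at 11.2, 3185 and 1701 CPM. Without the muscle list and Rn18s-rs5 in the totals, tumour 1 had 761 genes above and 1029 below. Muscle genes outside the list, such as Atp2a1, stayed in. These counts therefore do not show how much of the difference of tumour 1 comes from muscle.

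**Figure D4:**
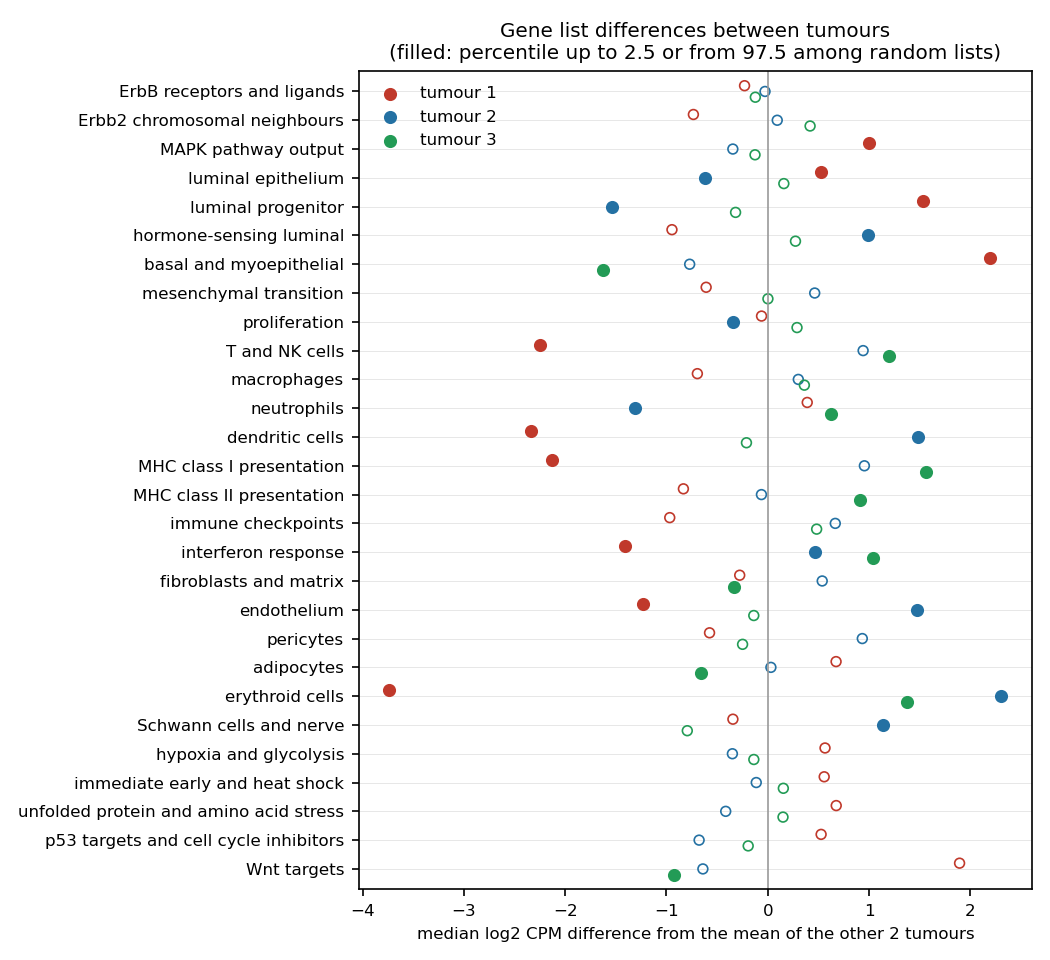
Median log2 CPM difference of each gene list's members from the mean of the other 2 tumours, for 28 lists and 3 tumours. Filled points stood apart from 10000 random lists of matched expression, and open points did not. Tumour 1 stands at 2.20 for basal genes and at −3.74 for erythroid genes.

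The remaining lists did not stand apart in any tumour with the filter, scaling and list medians described above. Medians in tumours 1, 2 and 3 were −0.23, −0.03 and −0.12 for ErbB receptors and ligands, −0.73, 0.09 and 0.42 for the chromosomal neighbours of Erbb2, −0.61, 0.46 and 0.00 for mesenchymal transition, −0.57, 0.93 and −0.25 for pericytes, 0.57, −0.35 and −0.14 for hypoxia and glycolysis, 0.56, −0.11 and 0.15 for immediate early and heat shock genes, 0.68, −0.41 and 0.15 for unfolded protein and amino acid stress, and 0.53, −0.68 and −0.19 for p53 targets and cell cycle inhibitors. Without the GC and length trend, hypoxia and glycolysis stood apart in tumour 3 (−0.44, percentile 0.11), immediate early and heat shock genes in tumour 1 (0.94, percentile 98.1) and unfolded protein stress in tumour 2 (−0.95, percentile 0.23). The chromosomal neighbours of Erbb2 stood apart in tumour 3 with a mean CPM of at least 1 (0.53, percentile 98.2), and pericytes in tumour 2 as a mean over members (1.17, percentile 98.9). Single members ranged widely. In tumours 1, 2 and 3 the endoplasmic reticulum chaperone gene Hspa5 was at 545, 128 and 243 CPM, Hyou1 at 330, 21.3 and 46.1, and Atf4 at 279, 273 and 391. The glycolytic genes Aldoa, Eno1 and Ldha were at 1422, 1752 and 1504 CPM, at 902, 294 and 457, and at 463, 109 and 191, and Egln3 at 93.1, 9.07 and 10.9. Junb was at 94.7, 871 and 485 CPM, Nr4a1 at 60.8, 131 and 114, Zfp36 at 46.7, 95.9 and 50, and Fos at 16.7, 0.870 and 3.75. Of the p53 list, Bax was at 65.5, 142 and 157 CPM and Phlda3 at 39.4, 157 and 143, whereas Mdm2 was highest in tumour 1. Sparc was at 823, 475 and 495 CPM, Vim at 384, 644 and 531, S100a4 at 8.28, 62.6 and 50.2, and Foxc2, below the filter, at 0.578, 1.12 and 0. Beside Des, Rgs5 was at 74.1, 237 and 97.8 CPM and Mcam at 82.3, 148 and 92.8. Beside Erbb2, Mien1 was at 35.9, 66.4 and 103 CPM and Stard3 at 40.8, 54.4 and 66.7. Of the keratinocyte and hair list, 1 of 12 members, Krt27, passed the filter, at 6.30, 3.85 and 4.39 CPM. Tchh was at 6.03, 0.373 and 0.445 CPM and Krt6a at 4.28, 0.497 and 0.381. The lists whose members varied more between tumours than random lists were basal (median SD 1.41), T and NK cells (1.32), neutrophils (1.54), dendritic cells (1.5) and erythroid cells (2.18).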

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

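The mean CPM filter of at least 1, GC and length correction, thinning, the totals without the listed muscle genes and Rn18s-rs5 and the basal list without smooth muscle genes were alternatives chosen after the data were seen. The luminal minus basal difference stayed positive in all alternatives, from 2.31 to 3.36, and the count of genes beyond counting noise (8098 to 16979) and of list pairs apart (22 to 36) stayed within 1.5 times. All 36 genes named as farthest apart kept their direction in 397 alternatives. They had been picked for gaps of at least 4-fold in the same data, so a turned direction was unlikely from the start. The coefficient of variation has no replicate spread and was taken as unchanged within 1.5 times. It ranged from 0.331 to 0.788 with each tumour left out, and 0.331 was the value without tumour 1. The cause of the changes below was not tested unless stated.

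The counts of genes apart depended on the threshold, the filter and, most in tumours 2 and 3, the tumour left out. Counts above and below are given for tumours 1, 2 and 3 in turn. A 2-fold threshold gave 2809 and 2632, 690 and 908, and 110 and 172. An 8-fold threshold gave 166 and 343, 1 and 4, and 0 and 0. Without a filter, with 23882 genes in place of 12710, they were 2360 and 1627, 597 and 859, and 295 and 266. With scaling by library totals they were 2060 and 458 in tumour 1, 8 and 215 in tumour 2, and 5 below in tumour 3. A mean CPM of at least 1 gave 1292 above in tumour 1, 75 and 458 in tumour 2, and 24 and 106 in tumour 3. A mean CPM of at least 5 gave 21 and 176 in tumour 2 and 25 below in tumour 3. Thinning gave 19 and 39 in tumour 2 and 5 and 5 in tumour 3. A prior count of 10 gave 49 below in tumour 2 and 4 and 6 in tumour 3, and GC and length correction gave 4 above in tumour 3. With each tumour left out, the counts ranged from 1255 to 1981 above and 1368 to 1879 below in tumour 1, 60 to 1879 and 82 to 1981 in tumour 2, and 82 to 1368 and 60 to 1255 in tumour 3, where each gene has 1 other tumour to differ from. The count of lists with an unusual spread was 3 with a mean CPM of at least 5, and 2 to 7 with each tumour left out.

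Of 1077 alternatives for single lists, 971 left the value unchanged, 98 moved it and 8 reversed it. Unchanged means a move smaller than the SD, over the tumours, of the list's median log2 CPM. Reversed means a turned sign in a pair that stood apart. The bound is wide for lists that differ much between tumours. Since a call rests on the percentile, it can end within this bound. GC and length correction brought proliferation in tumour 2 to 0.0207. Thinning brought dendritic cells in tumour 1 to 0.0393. Scaling by library totals brought interferon response in tumour 2 to −0.23. Its percentile stayed at 98.7, since that scaling shifts the median of all genes by −0.70 in tumour 2. Without tumour 1 and without tumour 2, values in tumour 3 were −0.0177 and 2.09 for T and NK cells, −0.90 and 3.48 for erythroid cells, 0.26 and −2.01 for Wnt targets, and −0.50 and 0.0211 for fibroblasts. Interferon response in tumour 2 was −0.0856 without tumour 1 and 1.26 without tumour 3. Scaling by library totals moved other lists that stayed apart by over 1.5 times, in tumour 1 to 1.85 for MAPK output, 1.38 for luminal epithelium, 2.38 for luminal progenitors, −1.43 for T and NK cells, −1.53 for dendritic cells, −1.28 for MHC class I, −0.57 for interferon response and −0.39 for endothelium, and in tumour 2 to −1.32 for luminal epithelium, 0.29 for hormone-sensing cells, −1.04 for proliferation, 0.80 for dendritic cells, 0.77 for endothelium and 0.43 for Schwann cells. Thinning left too few T and NK cell and Wnt target genes for a value, and a mean CPM of at least 5 too few of these and of dendritic cell genes. Of 30 list pairs apart, 13 stayed apart in every alternative that gave a value and 17 did not in at least 1, and 25 kept their call and direction after GC and length correction. Of the 54 other pairs, 25 stood apart in at least 1 alternative, 17 with all tumours kept and 16 with a tumour left out. GC and length correction added 7, MAPK output (−0.73), basal genes (−1.11) and unfolded protein stress (−0.95) in tumour 2, luminal progenitors (−0.63) and hypoxia (−0.44) in tumour 3, and hormone-sensing cells (−1.28) and immediate early genes (0.94) in tumour 1. List means added hormone-sensing cells (−1.01), checkpoints (−1.18) and Wnt targets (1.96) in tumour 1, pericytes (1.17) in tumour 2, and MAPK output (−0.13), luminal progenitors (−0.67), checkpoints (0.52) and hypoxia (−0.26) in tumour 3. Dropping the filter added Erbb2 neighbours (−1.10) and Wnt targets (1.999) in tumour 1, Wnt targets (−1.92) in tumour 2, and Erbb2 neighbours (0.48), dendritic cells (0.88) and Schwann cells (−0.92) in tumour 3. In tumour 3, Erbb2 neighbours and Schwann cells were added by a mean CPM of at least 5 (0.51 and −0.99) and of at least 1 (0.53 and −0.97), and in tumour 1 hormone-sensing cells by a mean CPM of at least 5 (−1.30). Depth limits low genes most in tumour 2, where 3 counts equal 0.373 CPM.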

Other observations

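The tests of the sequencing lane, of Myh3 and Myh8, of Igf2 and Fgf4, of shared reads and of the chromosome 12 run, and the trend removal and thinning as settings, were chosen after the result was seen, as were the genes named in this part, and no biological explanation was tested against a group.

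The growth factor genes Fgf4 and Fgf3 on chromosome 7 followed the same split between tumours, but not all genes near them did. Fgf4 (144847367 to 144865243) had 1 count in tumour 1, 640 in tumour 2 and 2456 in tumour 3, and Fgf3 (144838083 to 144844436) had 4, 59 and 55. Nearby, Fgf15 (9.50, 40.4 and 41.2 CPM) and Fadd (10.9, 45.6 and 48.9 CPM) were also lowest in tumour 1. Ppfia1 (55.7, 57.2 and 122 CPM) and Tpcn2 (8.89, 12.1 and 22.8 CPM) differed less, and Ano1 (104, 42.3 and 91.4 CPM) was highest in tumour 1. Oraov1, whose position was not available, had 998, 6871 and 22023 counts. On chromosome 10, the lysozyme gene Lyz1 had 20812, 7 and 2 counts, a value that is uncertain because its paralog Lyz2 can share reads. Lyz2 was at 478, 222 and 264 CPM. On chromosome 8, beside Cul4a, Lamp1 and Tfdp1, the genes Pcid2 (87.0, 520 and 258 CPM) and F10 (0.80, 16.4 and 4.19 CPM) went the other way.

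Tumour 1 had 1812 genes at least 4-fold apart, against 107 in tumour 2 and 20 in tumour 3. The hypothesis that a trend with GC content and transcript length between libraries could account for this was tested by removing the trend, after which 1550 genes were apart, among them 507 of the 769 above and 629 of the 1043 below. The hypothesis that the greater depth of tumour 1 could account for it was tested by thinning all libraries to the smallest total, which gave 1600 genes, among them 608 of the 769 above and 904 of the 1043 below. Neither accounts for most of the difference. The sequencing lane could not be examined, since 0 tumours were run in both lanes, so lane, library preparation and tumour remain joined.

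Skeletal muscle genes were abundant in tumours 2 and 3. That muscle tissue was included in these samples could not be settled, since 12 of 12 further muscle genes, chosen after the pattern was seen but before their own values were, were at least 4-fold higher in both tumours, as all 12 listed genes already had been, and muscle-like tumour cells could give the same. A muscle-like state with developmental myosins was argued against by Myh3 and Myh8, which made up 0.159% of myosin heavy chain counts in tumour 2 and 0.405% in tumour 3, and a mature state stays open. Whether the same muscle could be the source of Igf2 and Fgf4 also stays open, with log2 ratios of tumour 3 to tumour 2 of 0.59 and 0.97. These lie above the range of the first 12 genes (−1.497 to −0.23) and within that of all 24 (−1.497 to 1.15) only because of Myl1, the 1 muscle gene above them.

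A small part of the genes apart in tumour 1 lay in runs of neighbours. Of 704 protein-coding genes at least 4-fold above in tumour 1, 25 lay in the 4 windows described below. The shuffled orders treat neighbouring genes as unrelated, so a low share does not tell why neighbours were apart together. The fullest window of 10 genes held 7 above, which 0.003 of shuffled gene orders reached (0.016 adjusted over 6 scans). In total, 4 separate windows held more than the 5 genes at the 95th percentile of the fullest shuffled windows. Among them was chromosome 10 from 116905784 to 117792705, with Rab3ip, Cct2, Frs2, Mdm2, Slc35e3 and Nup107 apart. In the same window Yeats4, Lyz2, Cpsf6 and Cpm, between Frs2 and Mdm2, were not apart, with log2 gaps of 1.52, 0.86, 0.54 and 0.16. The hypothesis that chance placement could account for the runs was set in advance to fall at a share below 0.05, which was met at 0.003 and, with the GC and length trend removed, at 0.03, although that value adjusted over 6 scans was 0.094, and for genes below it was 0.01 and, without the trend, 0.0002 (adjusted 0.035 and 0.0012), with 7 genes on chromosome 7 from 142375911 to 143499334, Igf2 among them, and then 8 from 143069249 to 143685872. Without the trend the median gap of the 25 genes apart in the 4 windows was 2.40, which met the bound of 2 fixed for setting the trend aside. These genes had been picked for a gap of at least 2, so this median does not settle the runs as a set. The trend did not account for the genes apart in the chromosome 10 window, which kept gaps of 2.62 to 4.79. But 11 of the 25 fell below a gap of 2, and the chromosome 12 run kept a median of 1.43 and stays open. The windows on chromosomes 12 and 16 were not found without the trend, nor was that of genes below on chromosome 19 (5364638 to 5482517). Of the fullest, on chromosome 7 from 132931142 to 135716361, Ctbp2, Bccip and Dhx32 were found again. Of the 25 genes, 15 had an estimated count in tumour 1 within 0.01 of a whole number, as genes without divided reads have, and for the other 10 shared reads stay open. Among those 10 were Mdm2 and Nup107 on chromosome 10 and Ctbp2, Bccip and Dhx32 on chromosome 7.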
